A study of Caenorhabditis elegans with 2 samples.

How the data were processed

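Chromatin immunoprecipitation with sequencing (ChIP-seq) of the transcription factor ELT-2 was carried out in Caenorhabditis elegans embryos. ELT-2 is a GATA-type zinc finger protein of the intestine. Per the labels, the strain OP56 carries the integrated transgene wgIs56, which expresses ELT-2 with a C-terminal GFP and FLAG tag, on an unc-119 mutant background, and the fusion protein was precipitated with an antibody to GFP. Hermaphrodite late embryos were collected 4 hours after synchronization by egg bleaching, and chromatin was sheared by sonication. The 2 libraries are biological replicates 1 and 2 of 1 group, with the replicate numbers taken from the labels. Whether the replicates came from separate cultures is not given beyond the word biological, so the agreement between them covers whatever differed between these 2 samples. Control libraries were not analysed here, so no comparison between groups was made.

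The deposited files are 8 peak lists in narrowPeak format. For each of the genome builds ce11 and ce10 there is a list per replicate, a list called on the pooled replicates, and a thresholded list holding the pooled peaks that passed the irreproducible discovery rate (IDR) procedure, per the deposited file listing. The per-replicate and pooled lists are described there as peaks together with background, made as input for IDR, so most of their entries are weak. The aligner, the peak caller, their versions, the IDR threshold and the scale of the signal are not given in the sources used here. Each peak carries a signal value, a −log10 q-value and a summit position, all of which are the authors' own deposited values. The signal is never negative and was used here to describe, rank or filter peaks within a list. The −log10 q-value was used to describe the lists. Replicate agreement had already entered the thresholding, and the pool holds both replicates. The presence of thresholded peaks in both replicates is therefore not independent evidence of agreement. In ce11 the thresholded peaks were those of highest signal in the pool, and not each was strong in both replicates. Of the 4098, 3130 (76.4%) matched an entry among the 4098 strongest of each replicate.

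The numbers of reads per library are not known from these lists, and no depth can be stated. The ce11 lists held 25770 peaks for replicate 1, 25986 for replicate 2, 30000 for the pool and 4098 after thresholding. Coordinates of ce11 peaks were read against the WBcel235 assembly, which is the same assembly, and the Ensembl annotation of release 115. All ce11 peaks lay within its chromosome lengths. Coordinates in ce10 were not converted, and the ce10 lists were used for counts, overlaps within that build and signal levels. Positions are given 1-based.

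A promoter window reached from 1000 bp upstream to 200 bp downstream of the 5′ end of any transcript of a protein-coding gene, and a gene had a promoter peak when a thresholded summit fell in its window. One peak can therefore count for more than 1 gene. Shares of summits in promoter windows and within 200 bp of tRNA genes were compared with 1000 circular shifts of the summits within each chromosome, in a one-sided permutation test whose smallest possible p is 0.001. The replicates were compared over the 4098 peaks of highest signal in each, with an overlap of at least 1 bp, against 1000 shifts of replicate 2. The share of peaks on chromosome X was tested with a two-sided exact binomial test against the share of protein-coding genes on X. The sequence TGATAA, the core ELT-2 site, was searched on either strand within 50 bp of each summit and in a window of the same width centred 500 bp to the left, and peaks with a site in exactly 1 of the windows entered a two-sided exact sign test. The reversed word AATAGT, which has the same base composition, served as a control. Spearman's rho between site presence and signal was tested with 100000 permutations across peaks, which are not independent replicates.

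Before the data were examined, 19 gene lists were fixed: the endoderm GATA cascade, intestinal lumen and brush border, intestinal hydrolases and lysozymes, vitellogenins, metal homeostasis, lipid metabolism, gut granule and lysosome, innate immunity, stress and metabolic transcription regulators, vacuolar ATPase, detoxification enzymes of the cyp, ugt and gst families, nuclear hormone receptors, body wall muscle, pharynx, epidermis, collagens, neurons, germline and ribosomal proteins. Each list was compared with all other protein-coding genes, 19985 in total, by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 19 lists. Genes named in the text were set by a rule also fixed before the data were examined. It takes every member of the endoderm GATA cascade, the genes at the 20 thresholded peaks of highest signal, the 3 members of each list with the strongest promoter peak, and 13 genes fixed by name (act-5, ges-1, ifb-2, asp-1, elt-2, elt-7, pho-1, mtl-1, mtl-2, ftn-1, spp-1, vit-2 and unc-119). Any other gene named was chosen after its values were seen. Intervals are 95% exact Clopper-Pearson for shares and 95% conditional exact for odds ratios, and they cover counting error only. The exception is the Mantel-Haenszel odds ratio matched on signal quintile, whose 95% interval is a large-sample approximation.

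The alternatives tried were other promoter windows, assignment to the nearest 5′ end, a stricter signal threshold, the ce10 lists, other overlap rules, other site definitions and windows, other distances, and each replicate's own top 4098 peaks in place of the thresholded list, which leaves out the other replicate. Leaving out the mitochondrial peaks, and every alternative for the comparison of lists with markers of other cell types, were added after seeing the data. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, with figures drawn in matplotlib 3.10.9. The promoter share, the list test, the TGATAA share and its relation to signal were tested on simulated data. A planted list of 25 genes was called in 100% of 100 runs over 19985 genes, and a random list in 6% of them. Other list sizes and weaker excesses were not simulated, so the power for lists of 6 or 7 genes is unknown. Planted promoter and TGATAA excesses over 4098 peaks were called in 100% of 20 runs each, and unplanted ones in 0%. A planted trend of sites with signal was called in 100% of 20 runs and an absent one in 10% of 20. For replicate overlap only the recovered share was checked, with a largest error of 1.46 percentage points over 5 runs, and the tests of chromosome X and of tRNA genes were not simulated.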

Results

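The data are lists of ChIP-seq peaks of tagged ELT-2 in late embryos of C. elegans, from 2 biological replicates. A listed peak is a called position, and whether ELT-2 binds there was not tested against a control here. ELT-2 is the main GATA factor of the worm intestine after the endoderm has been specified. The thresholded ce11 list held 4098 peaks, which were the 13.7% of the pooled 30000 peaks with the highest signal. Peak signal, the authors' own value, ran from 67.6 to 1740 with a median of 108, and the median width was 456 bp. In ce10 the thresholded list held 4117 peaks. The sequencing depth of the libraries is unknown.

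None of the 20 strongest peaks lay in the promoter window of a gene from the fixed lists. Of these 20 peaks, 3 were on the mitochondrial genome, including the first, with a signal of 1740 and a summit at position 12451 in a coding exon of WBGene00010967. The other mitochondrial peaks of this group lay at WBGene00000829 and WBGene00010964. Among nuclear peaks the strongest had its summit at position 2378735 of chromosome II, 884 bp upstream of F16G10.6, with a signal of 1382 and a TGATAA site. The next lay 531 bp upstream of K12H4.5 on chromosome III, with a signal of 1117 and no TGATAA within 50 bp. Peaks in promoter windows of this group also lay at srz-62, fbxc-29, sre-23, M01F1.9, ears-2, C16A11.2, clec-78 and T24E12.13. The remaining peaks were outside promoter windows and nearest to Y37A1A.2, wdr-83, F55C5.17, mpk-2, W03C9.1, zig-13 and cutl-18. The wdr-83 peak at position 5032817 of chromosome II lay inside a tRNA gene.

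The replicates listed largely the same strong regions. Of the 4098 strongest peaks of replicate 1, 3188 (77.8%) overlapped one of the 4098 strongest of replicate 2, against a mean of 3.93% and a maximum of 4.93% over 1000 shifts (one-sided permutation p = 0.001, the smallest possible). The peak upstream of cpr-6, a cathepsin B-like protease gene, ranked 59 in replicate 1 and 63 in replicate 2, and that upstream of lys-8, a lysozyme gene, ranked 86 and 75. Ranks lay farther apart for ifb-2 (242 and 588), ifo-1 (445 and 939) and act-5, the actin gene of the intestinal brush border (818 and 3313). Across the 4089 thresholded peaks with a match in both lists, Spearman's rho between the replicates' signals was 0.751, and the log2 ratio had an SD of 0.47. With summits required to lie within 100 bp the shared share was 70.1%.

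**Figure D1:**
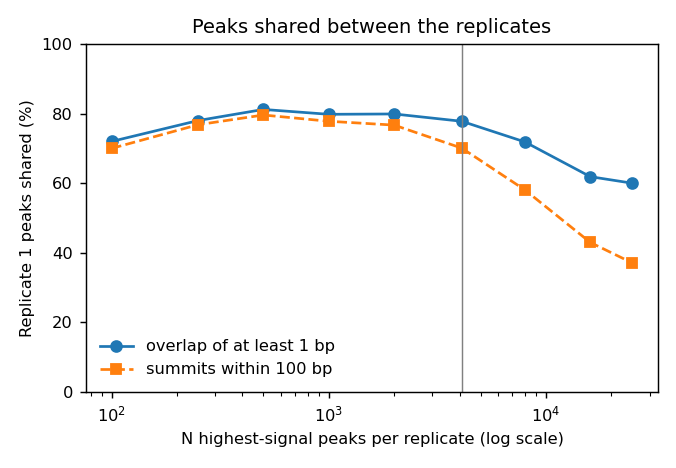
The x axis is the number N of highest-signal peaks taken from each replicate on a log scale, and the y axis is the percentage of replicate 1 peaks shared with replicate 2. Circles count overlaps of at least 1 bp, squares count summits within 100 bp, and the grey line marks N = 4098, where the shares were 77.8% and 70.1%.

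ELT-2 peaks were concentrated near the 5′ ends of genes. Of 4098 summits, 2344 (57.2%) fell in a promoter window, against a mean of 26.3% and a maximum of 28.3% over 1000 shifts (one-sided permutation p = 0.001, the smallest possible). These peaks covered 2734 of 19985 protein-coding genes (13.7%), and 596 of them lay in the windows of more than 1 gene. By annotation, 65.9% of summits were intergenic, 23.3% in introns, 4.59% in coding exons, 4.15% in 5′ UTR exons and 2.03% in 3′ UTR exons. The intronic summits included those of the haem transporter gene hrg-1 (chromosome X, 4008992 to 4009217, signal 286) and of the fatty acid desaturase gene fat-4 (chromosome IV, 9801538 to 9801770, signal 299).

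Chromosome X held more peaks than its number of genes would give. It carried 834 of 4098 peaks, or 20.4% (95% exact interval 19.1 to 21.6%), against 13.7% of protein-coding genes (two-sided exact binomial p = 7.27e-32). Per 100 protein-coding genes there were 30.5 peaks on X and between 13.8, on chromosome V, and 23.9, on chromosome III, on the autosomes. Against the 17.7% of base pairs that lie on X the excess was smaller (exact binomial p = 9.61e-06). Per Mb there were 47.1 peaks on X, 46.8 on II, 45.8 on III and between 32.8 and 39.8 on the other autosomes, so by length X did not stand apart from II and III. Looked at after the data had been seen, 442 of the 834 peaks on X lay outside promoter windows. A promoter peak was found at 14.8% of protein-coding genes on X, against 13.7% of all protein-coding genes. The excess over the gene share is therefore not one of X-linked genes with a promoter peak to a like extent. The X-linked peaks included those of cpr-6, of the lipid-binding protein gene lbp-3 and of ugt-46.

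The ELT-2 core site marked the summits. TGATAA lay within 50 bp of 1784 of 4097 summits (43.5%) and in 9.57% of the flanking windows (two-sided exact sign test p = 1.42e-260). The share at summits was 27.9% within 25 bp, and 26.1% for the longer site TGATAAG within 50 bp. The control word AATAGT was found at 7.05% of summits and in 7.22% of flanks (exact sign test p = 0.796). Peaks of cpr-6, lys-8, ifb-2 and lbp-3 carried the site, and those of act-5, mtl-2 and rpl-3 did not. The share with TGATAA was 54.6% (95% exact interval 51.2 to 58.1%) in the signal quintile of strongest peaks and 33.8% (30.6 to 37.2%) in the weakest. Across peaks, Spearman's rho between site presence and signal was 0.15 (two-sided permutation p = 1e-05, the smallest possible).

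**Figure D2:**
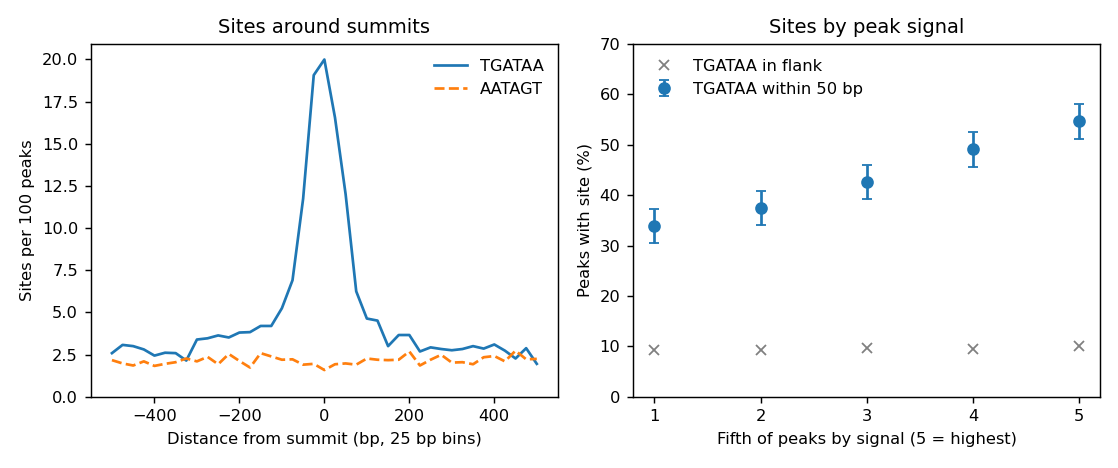
The left panel plots sites per 100 peaks in 25 bp bins by distance from the summit in bp, for TGATAA and for the control word AATAGT. The right panel plots the percentage of peaks with TGATAA within 50 bp of the summit (points, with 95% exact intervals) or in the flank (crosses) by signal quintile, rising from 33.8% in quintile 1 to 54.6% in quintile 5.

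Genes that build the intestinal lumen carried ELT-2 peaks far more often than other genes. Of 18 members of the lumen and brush border list, 12 (66.7%) had a promoter peak (odds ratio 12.7, 95% interval 4.4 to 41.2, Fisher's exact test, adjusted p = 3.32e-06). The strongest lay upstream of the intermediate filament gene ifb-2 (chromosome II, 5749877 to 5750052, signal 263), of bbln-1 (signal 215) and of ifo-1 (signal 208), whose products organise the filament sheath below the brush border. The act-5 peak (chromosome III, 13606019 to 13606474, 181 bp upstream) had a signal of 139. Among hydrolase and lysozyme genes, 13 of 26 had a promoter peak (odds ratio 6.33, 95% interval 2.7 to 14.8, Fisher's exact test, adjusted p = 6.57e-05), led by cpr-6 (signal 434), lys-8 (signal 404) and cpr-4 (signal 253). With replicate 1's own 4098 peaks, which leaves out replicate 2, the odds ratio of the hydrolase list was 3.92 (exact adjusted p = 0.00593). Among the 13 genes, lipl-5 and asp-5 had peaks with no match in the full list of replicate 1, though 4092 of the 4098 thresholded peaks had one. The carboxylesterase gene ges-1, a classic intestinal marker, had a peak with TGATAA at chromosome V, 1433020 to 1433475, with a signal of 159. Its summit lay 1111 bp upstream, beyond the 1000 bp window, so it was not counted. The genes asp-1, pho-1 and spp-1 had no promoter peak, and their nearest thresholded summits lay 2685 bp upstream, 7801 bp downstream and 2167 bp upstream of a 5′ end.

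Lists of metabolic and stress genes also had promoter peaks more often than other genes, though not every list under every alternative. Metal homeostasis genes had promoter peaks in 7 of 16 cases (odds ratio 4.92, 95% interval 1.55 to 14.9, Fisher's exact test, adjusted p = 0.00896), led by hrg-1, the manganese transporter gene smf-3 (signal 188) and the ferritin gene ftn-1 (signal 151). The metallothionein gene mtl-2 had a peak shared with T08G5.1 (signal 108), and mtl-1 had none. Lipid metabolism genes had them in 9 of 27 cases (odds ratio 3.16, exact adjusted p = 0.0181), led by lbp-3 (signal 349), fat-4 and daf-22, an enzyme gene of peroxisomal beta-oxidation (signal 162). Stress and metabolic transcription regulators had them in 8 of 20 cases (odds ratio 4.22, exact adjusted p = 0.00896), led by pha-4 (signal 186), zip-2 (signal 168) and xbp-1 (signal 162). Detoxification genes had them in 45 of 185 cases (odds ratio 2.05, exact adjusted p = 3.42e-04), led by ugt-46 (signal 372), ugt-64 (signal 252) and ugt-53 (signal 213). By family, in a comparison made after the data had been seen, ugt had 23 of 67 (odds ratio 3.32, exact adjusted p = 3.71e-04 over 175 families), while cyp with 13 of 74 (1.35, adjusted p = 0.572) and gst with 9 of 44 (1.62, adjusted p = 0.382) did not differ from other genes past the threshold. For metal homeostasis, the adjusted p was 0.0525 with a window of 500 bp upstream to 100 bp downstream and 0.0847 with assignment to the nearest 5′ end. With the 2049 strongest peaks it was 0.278 for lipid metabolism and 0.134 for the stress regulators. A window of 2000 bp upstream to 500 bp downstream raised the odds ratios of these 2 lists to 4.91 and 6.84, and the nearest 5′ end raised that of the stress regulators to 11.9. The tests did not adjust for the number of 5′ ends of a gene or the length of sequence around it, so these rises are not added support.

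Ribosomal protein genes were also covered. Of 78 members, 50 (64.1%) had a promoter peak (odds ratio 11.5, 95% interval 7.06 to 18.9, Fisher's exact test, adjusted p = 1.91e-23), led by rpl-3 (chromosome III, 3867395 to 3867773, signal 493), rpl-22 (signal 472) and rpl-15 (signal 390). The odds ratio was 3.19 with assignment to the nearest 5′ end (exact adjusted p = 2.13e-05) and 6.26 with the 2049 strongest peaks (exact adjusted p = 1.31e-09). Of the 51 promoter peaks of this list, 3 (5.88%, 95% exact interval 1.23 to 16.2%) carried TGATAA. That interval includes the 9.57% of flanking windows of all peaks with TGATAA. The lumen and brush border list had 14 promoter peaks, of which 11 (78.6%) carried it, and the hydrolase list 12 of 13. Of the 50 ribosomal protein genes, 38 had peaks that also lay in the window of another gene. With unshared peaks alone, 12 of 78 genes had one and the odds ratio was 2.09 (95% interval 1.02 to 3.9).

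Markers of other tissues carried few ELT-2 peaks. Collagen genes, expressed in the epidermis, had promoter peaks in 5 of 156 cases (odds ratio 0.207, 95% interval 0.0664 to 0.496, Fisher's exact test, adjusted p = 8.53e-05, lower than other genes), with the strongest at col-185, col-71 and col-38. Promoter peaks were found at 1 of 20 body wall muscle genes (deb-1), 1 of 24 epidermal genes (nhr-25), 1 of 26 neuronal genes (rab-3) and 2 of 22 germline genes (cgh-1 and spn-4). None was found at 15 pharyngeal genes, which allows a share of up to 21.8%. None of these 5 lists passed the threshold on its own, with adjusted p between 0.429 and 0.848. Their values were not stable. Without replicate 1 the odds ratio rose from 0.252 to 0.829 for neurons, from 0.274 to 0.577 for epidermis and from 0.332 to 1.12 for muscle. It was 1.69 for epidermis with the nearest 5′ end and 1.31 for germline with the 2049 strongest peaks. Together the 5 lists had 5 of 107 genes with a peak (4.67%), 10 without replicate 1 (9.35%) and 12 with the nearest 5′ end (11.2%). Of the 14 other lists, 10 exceeded them (Fisher's exact test, adjusted over the 14), against 8 without replicate 1 and 6 with the 2049 strongest peaks, and this adjustment and these alternatives were added after the data had been seen. The odds ratio was 38.0 for the lumen list (exact p = 5.05e-09, adjusted 3.54e-08) and 35.5 for ribosomal proteins (exact p = 2.66e-19, adjusted 3.72e-18), so this contrast is not particular to intestinal genes. Without replicate 1 they were 18.6 and 12.3, and with the nearest 5′ end 15.2 and 4.90, all 4 with an exact adjusted p under 0.05. Nuclear hormone receptors (adjusted p = 0.00371), immunity (0.0380) and vacuolar ATPase genes (0.0477) also exceeded these markers by the exact test, but not without replicate 1 (adjusted p = 0.256, 0.0651 and 0.0855). With the 2049 strongest peaks none of them passed either (exact adjusted p = 0.0759, 0.0672 and 0.224). Other windows and the nearest 5′ end gave mixed calls. Without replicate 2 all of them passed (exact adjusted p = 0.00794, 0.00800 and 0.00358).

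The remaining lists did not pass the test. Of the endoderm GATA cascade, 1 of 7 genes had a promoter peak, elt-7, whose product acts alongside ELT-2 (chromosome V, 4770393 to 4770848, 49 bp upstream, signal 111, with TGATAA). A peak with TGATAA and a signal of 236 lay in the 3′ UTR of end-1, 1914 bp downstream of its 5′ end, and med-1, med-2, end-3, elt-2 and elt-4 had none in their promoter windows. The genes elt-2 and elt-4 lie in an interval without any summit even in the pooled list with its weak entries. Their lack of a promoter peak therefore does not show that ELT-2 is absent there. Vitellogenin genes, which encode yolk proteins made in adults, had 0 of 6, vit-2 among them. Promoter peaks were found at 3 of 13 gut granule genes (lmp-1, pgp-2 and apm-3), 4 of 18 immunity genes (led by irg-4, vhp-1 and atf-7), 4 of 20 vacuolar ATPase genes (led by vha-2, vha-12 and vha-1) and 39 of 269 nuclear hormone receptor genes (led by nhr-291, nhr-68 and nhr-88). Adjusted p values of these 6 lists lay between 0.469 and 1. With replicate 2's own 4098 peaks, which leaves out replicate 1, the gut granule list passed at an adjusted p of 0.0488.

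**Figure D3:**
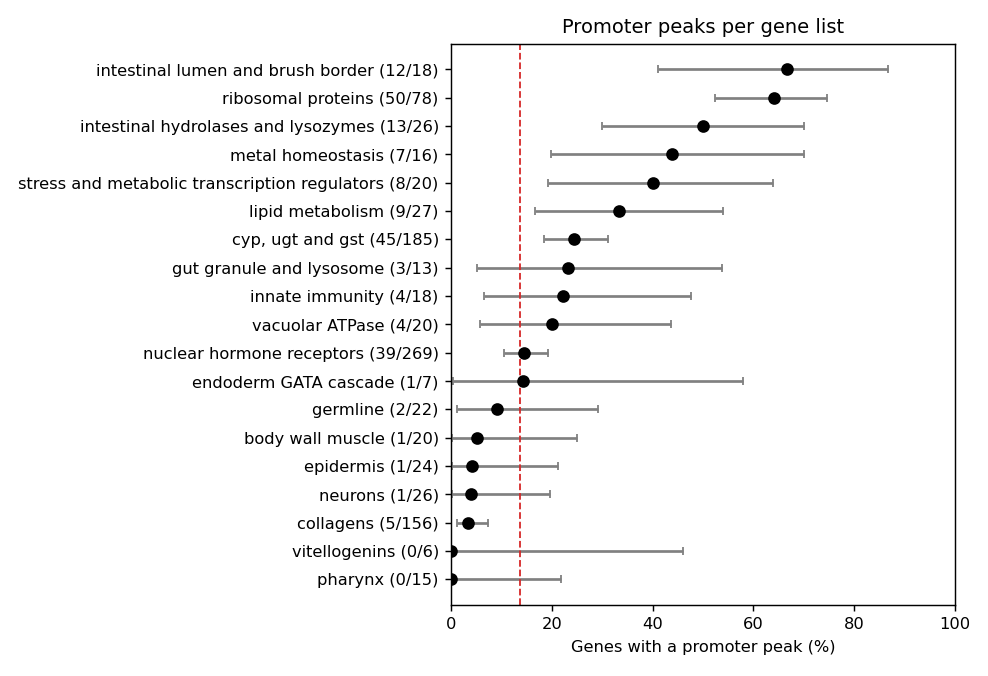
The x axis is the percentage of each list's genes with a promoter peak, with 95% exact intervals, and the counts stand beside the list names. The dashed line marks the 13.7% of all protein-coding genes, and the lumen list (66.7%) and ribosomal proteins (64.1%) lie farthest above it.

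ELT-2 peaks also lay at tRNA genes. Of 4098 summits, 247 (6.03%) were within 200 bp of a tRNA gene, against a mean of 0.476% and a maximum of 0.903% over 1000 shifts (one-sided permutation p = 0.001, the smallest possible). Without the mitochondrial peaks the share was 5.86%. At 229 of 612 nuclear tRNA genes (37.4%) a summit lay within 200 bp. TGATAA was found at 27 of the 239 nuclear peaks near tRNA genes (11.3%) and at 45.8% of the other nuclear peaks (odds ratio 0.151, 95% interval 0.0967 to 0.227, Fisher's exact test, p = 7.33e-29).

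Around the gene elt-2 itself no thresholded peak was listed. The count within 20 kb of elt-2 (chromosome X, 10481240 to 10483441) was 0, as it was for unc-119 (chromosome III, 10902641 to 10908935), and the median over all protein-coding genes was 2. Both genes concern the transgene, which carries elt-2 and was made in an unc-119 mutant strain. Within 50 kb there were 3 peaks around elt-2 and 2 around unc-119, against a median of 4. Fewer peaks than these were found around 28.9% and 15.1% of protein-coding genes, so the counts within 50 kb were not rare. How many genes had 0 within 20 kb was not determined. The elt-4 gene lies in the same empty interval as elt-2. In the pooled list, including its weak entries, the last summit before elt-2 was at 10441124 and the first after it at 10511825, and the strongest promoter entry of unc-119 had a signal of 27.2. These values describe the entries used here, and whether ELT-2 occupies either locus was not analysed here.

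**Figure D4:**
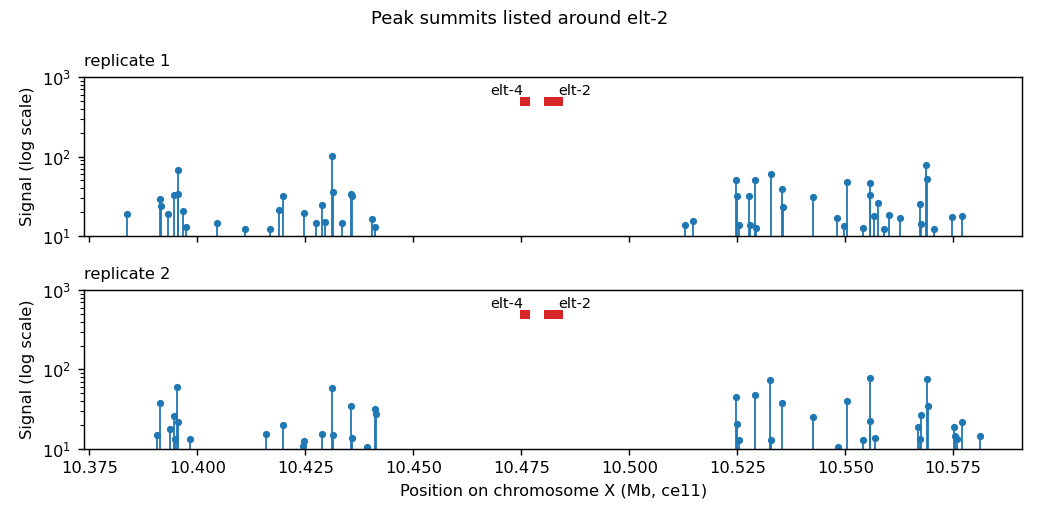
Peak summits of replicate 1 (top) and replicate 2 (bottom) by position on chromosome X in Mb (ce11), with the authors' signal on a log scale, and the genes elt-2 and elt-4 as red bars. No summit is drawn between 10441146 and 10512801 in replicate 1, or between 10441248 and 10524737 in replicate 2.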

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

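The signal levels below were looked at only after the data had been seen. The ce10 list of replicate 1, which the report's comparisons between genes do not use, stood apart from the ce11 list of the same replicate: its 1000th highest signal was 2.0 times as high (172.9 against 86.6), and it held 30000 peaks against 25770. The ratio was 2.00 at the 100th and 1.99 at the 4000th highest peak of replicate 1, and between 0.991 and 1.00 at these ranks in replicate 2. The pooled ce10 list, from which the ce10 thresholded list was taken, was 1.52 to 1.54 times as high as the pooled ce11 list at the same ranks.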

How the results depend on the processing

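Of 184 alternatives, 168 kept the direction and the side of the threshold, or a count within 1.5 times, and those without mitochondrial peaks or on lists above other cell types were chosen after seeing the data. The promoter, chromosome X, TGATAA, tRNA and replicate overlap results kept both under each alternative run. The 168 include alternatives that could hardly change a call, so they overstate how much was tested. Leaving out the mitochondrial peaks changed no count of genes with a promoter peak in the 14 lists compared with other cell types. Lists that stayed short of the threshold, such as the vitellogenins with 0 of 6 genes, also count as kept. Lists above other cell types fell from 10 to 6 with the 2049 strongest peaks. The peak count fell to 2049 above the median signal, by construction, and the count around elt-2 was 3 within 50 kb. Odds ratios that lost their call were 3.81 (window of 500 bp upstream to 100 bp downstream) and 3.05 (nearest 5′ end) for metal homeostasis, and, with the 2049 strongest peaks, 2.28 for lipid metabolism and 3.27 for the stress regulators, where fewer peaks were tested. Lists never past the threshold changed direction 8 times. With a window of 2000 bp upstream to 500 bp downstream the odds ratio was 0.758 for the endoderm GATA cascade and 0.888 for nuclear hormone receptors. With the nearest 5′ end it was 0.896 for the vacuolar ATPase and 1.69 for epidermis, and with the 2049 strongest peaks 1.31 for germline. Leaving out 1 replicate gave 2.78 to 3.98 for the gut granule list, 0.967 to 0.982 for nuclear hormone receptors and 0 to 1.12 for body wall muscle. Apart from the changes by construction, the cause was not tested. No depth is known, so its effect cannot be stated.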

Other observations

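The gene families and RNA classes in the first paragraphs, the split of X-linked peaks and the tests on the elt-2 interval were chosen after the data had been seen, and the tests on ribosomal and mitochondrial peaks were set before their results were seen, except that the use of the exact interval for the mitochondrial share was added after its count was known. Among 175 families of at least 10 genes that share a name prefix, 14 had promoter peaks more often than other genes and 15 less often (Fisher's exact test, adjusted p under 0.05 over the families). Families with more peaks that mostly carried TGATAA, against 38.2% of all promoter peaks, were ugt (23 of 67 genes, 70.8% of peaks with the site), the peroxisome assembly genes prx (7 of 11 genes, 66.7%), zip (6 of 12 genes, 62.5%), mig (7 of 16 genes, 71.4%) and dod (5 of 10 genes, 80% of peaks). Others had more peaks and few sites: nuclear pore genes npp (12 of 26 genes, 0 of 12 peaks with TGATAA), translation initiation factor genes eif (10 of 25 genes, 0 of 11), cytochrome oxidase genes cox (7 of 15 genes, 0 of 7), Mediator genes mdt (8 of 20 genes, 0 of 9) and chaperone genes dnj (10 of 29 genes, 0 of 13). Of 19 chemoreceptor families, 9 had fewer, among them str (3 of 193 genes), srh (7 of 220) and srx (0 of 101), and 10 did not pass, with adjusted p from 0.0615 (sra) to 0.618 (srv). The clec family also had fewer, with 15 of 240 genes (odds ratio 0.417, Fisher's exact test, adjusted p = 0.00412), although clec-78 lay at 1 of the 20 strongest peaks.

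Of small RNA genes, 85 of 346 snoRNA genes (24.6%) had a thresholded summit within 200 bp, and 89 nuclear peaks (2.18%) lay there against a shifted mean of 0.184% (one-sided permutation p = 0.001, the smallest possible), 7 of them with TGATAA. Summits near snRNA genes numbered 24, with TGATAA at 0. Near piRNA genes the share was 1.64% of peaks against a shifted mean of 2.88%. On chromosome X, 392 of 834 peaks were in promoter windows against 59.7% on the autosomes (odds ratio 0.6, 95% interval 0.513 to 0.701, Fisher's exact test, p = 6.65e-11), so X held 25.3% of the peaks outside promoters and 16.9% of those inside. Of the base pairs in promoter windows, 14.7% lay on X. The lower promoter share on X therefore does not mean that its promoters held fewer peaks for their length.

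Peaks at ribosomal protein genes rarely held the ELT-2 site (3 of 51), against 895 of 2344 promoter peaks overall (38.2%), 50.7% of other peaks, and 2 of 6 peaks at markers of other cell types, too few to tell apart from the overall share. TGATAA was at 24 of 28 promoter peaks of the 3 intestinal marker lists (endoderm GATA cascade, lumen, hydrolases; 85.7%) and at 5 of 57 peaks of ribosomal and other markers pooled (8.77%), which are mostly ribosomal, an odds ratio of 56.7 (95% interval 13.2 to 327, Fisher's exact test, p = 1.94e-12). Weaker signal does not account for it, since the Mantel-Haenszel odds ratio matched on signal quintile was 37.4 (approximate 95% interval 10.6 to 132, from small counts per quintile). Windows shared with a neighbouring gene hold most of the ribosomal peaks but not all of the excess, since with unshared peaks alone 12 of 78 genes had one and the odds ratio was 2.09 (95% interval 1.02 to 3.9, Fisher's exact test, p = 0.0327), a bound close to 1. Occupancy of open or highly occupied promoters without a GATA site may underlie the ribosomal peaks, as a hypothesis, but no control precipitation was analysed here, no biological explanation was tested, and lists outside this test varied, with TGATAA at 5 of 9 lipid metabolism peaks, 5 of 9 stress regulator peaks and 1 of 4 gut granule peaks.

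The 22 mitochondrial peaks had a median signal of 380 against 108 for nuclear peaks and covered 76.6% of the mitochondrial genome. TGATAA was at 1 of their 22 summits, or 4.55% (95% exact interval 0.115 to 22.8%), and 92.7% of 10000 draws of 22 random mitochondrial positions gave a share as high or higher. That is consistent with high-copy mitochondrial DNA being called without a binding site. Binding at GATA sites there cannot be told apart from chance, since the interval reaches past the 95th percentile of the draws, 22.7%, although the share was below the nuclear 43.7% (two-sided exact binomial p = 1.04e-04).

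The interval around elt-2 without a listed summit was 71655 bp long in replicate 1 and 83489 bp in replicate 2. In the pooled list it was 70701 bp, where the density of chromosome X would give 18.8 summits. A chance gap is an unlikely account but not excluded, since 1.80% of protein-coding genes in replicate 1, 0.896% in replicate 2 and 3.69% in the pooled list lay in a gap as long, and the pooled list held 30 such gaps. Extra copies of the tagged region in the transgene or in the control, filtering, and entries not used here cannot be told apart. The pooled list held 0 summits within 20 kb of elt-2, but whether each account would give that count was not tested. No read coverage was analysed here. No biological explanation was tested.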
